A study of Triticum aestivum with 24 samples.

How the data were processed

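The series measured RNA in leaves of 2-week-old wheat seedlings on a single-colour Agilent array, with Cy3-labelled cRNA and 1 array per sample. Per the labels' protocols, plants grew on soil at 22 ºC with 16 h of light and 8 h of dark, total RNA was extracted with a column kit, and cRNA was made with a linear amplification kit. The 24 arrays fall into 8 groups of 3: the common wheat cultivar Chinese Spring (CS) and 7 lines in which a chromosome of the barley cultivar Betzes had been added to Chinese Spring. The line 1HS carries the short arm of barley chromosome 1, and 2H, 3H, 4H, 5H, 6H and 7H carry the chromosome of that number. The series design calls the 3 replicates of a line independent samples; whether each came from 1 plant or a pool is not given in the sources used here.

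The deposited scanner files hold 1 fluorescence intensity per spot on a linear scale, written by Agilent Feature Extraction 9.5 per the submitters' processing notes and by version 9.5.1.1 per the file headers. The processed signal is an intensity from which the scanner software has subtracted background, per the file headers, and the mean signal and local background are intensities before that step. Flags in the deposited files mark whether each spot was well above background, positive and significant, saturated or a population or non-uniformity outlier. The series matrix holds the same processed intensity as the scanner files, since all 907824 values deposited in both were equal, so its scale is linear and no centring was applied. Its column medians ran from 67.3 to 264.

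Control spots were left out, which left 37826 probes of 60 bases, each with 1 spot per array. The values compared are log2 of the processed signal minus the 75th percentile of that log2 signal on the same array, called the scaled log2 signal. A probe was tested if it was well above background on all 3 arrays of at least 1 of the 8 groups, which kept 25190 probes (66.6%). One limma model (version 3.58.1, in R 4.3.3, with the data.table package at version 1.17.8) with a mean per group was fitted to all 24 arrays. Each line minus CS was a contrast, tested on both sides with moderated statistics and Benjamini-Hochberg adjustment per contrast, at an adjusted p below 0.05. The p-values measure the spread between the arrays of a group, which in this fit includes the spread between scan days. Outlier flags were not used to drop spots, so that every probe has 3 values per group, and no array had more than 4 saturated probes.

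A probe that was well above background on no array of a group has only a bound there. Its difference is then given as at least N-fold: the mean of the bright group against the dim group's mean of, on each array, the higher of the lowest scaled signal among probes well above background and the probe's own value. That lowest signal ran from -7.56 to -3.46 on the log2 scale across arrays, so bounds depend on the array. Dim probes can share the same value on an array. On 1HS replicate 1, wheat0130Contig12368 and rwhsc1j08_195 were both at -6.56. The SD of a dim group, and SEs and p-values that use it, can therefore partly reflect the low end of each array.

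The number of probes well above background is the depth of an array. It was 20917 to 23477 in replicate 1, 26292 to 32046 in replicate 2 and 30459 to 33246 in replicate 3. The lowest count in replicate 2 belonged to the 1HS array, and the next lowest in that replicate was 30720. The number of arrays limits the precision of every value.

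The file headers place the arrays on 6 slides of 4, scanned on 3 days, and each day holds 1 replicate number. On each day a slide held 1HS, 2H, 3H and 4H, and another held 5H, 6H, 7H and CS, in the same order each time. To check whether replicate numbers pair the samples, each array's deviation from its group mean was correlated with that of the CS array of the same number over the tested probes. All 21 correlations lay between 0.43 and 0.71, across probes, which are not independent replicates, so the numbers were taken as pairs. The fit with the replicate number as a block is therefore given beside the main counts. It is also the fit with the scan day as a block, and it does not remove differences between the slides of a day. Lines 1HS, 2H, 3H and 4H never shared a slide with CS, so their differences from CS are also differences between slides. Within a day each group has 1 array, so no test can be made there, and the day-by-day differences are given for the probes named.

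On simulated arrays with the probe means, spread and replicate effects of these data, 100 probes were changed by 2-fold and 100 by 4-fold in 5H among 25190 probes. The fit without a block recovered 16 and 60 of them with 0 false calls in that contrast. With the replicate number as a block it recovered 47 and 86, with 9 false calls.

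The files name almost every probe by a sequence contig or cDNA clone, and the wheat gene table at hand holds no sequences, so probes could not be assigned to genes or chromosomes. Tests of gene lists, of markers of other tissues and of wheat chromosome groups, planned before the data were examined, were therefore not run. By the rule set then, at most 2 probe IDs that rose and 2 that fell are given per line: those with the largest log2 difference among probes with an adjusted p below 0.05 whose 3 line arrays all lay on 1 side of the 3 CS arrays. Probes detected in a single line, and up to 5 probes called in the most lines, are added. Probes named for setting 1 line apart from all other arrays were chosen after their values were seen.

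Alternatives tried were the replicate block, normexp background correction of the mean signal with an offset of 50, quantile normalization, scaling by the median of probes detected on all arrays, the series matrix, no filter on dim probes, a stricter filter, the 6 arrays of a comparison alone, a 2-fold minimum, the other 6 lines as the reference, slides as a random or fixed block, and leaving out each array of a comparison. Under normexp the median difference of all tested probes was 0.21 in 1HS and 0.19 in 6H on the log2 scale, and in the other 5 lines it was within 0.04 of 0. Normalized by the 75th percentile, the median lay between -0.04 and 0.01 in all 7 lines.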

Results

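RNA levels in seedling leaves were compared between common wheat and 7 wheat lines that each carry 1 added barley chromosome or chromosome arm. Each of the 8 groups had 3 arrays, 1 from each of 3 scan days. Of 37826 probes, 25190 were well above background on all 3 arrays of some group and were tested. Arrays of the same replicate number resembled each other more than arrays of the same line did. Over the tested probes, the median correlation was 0.966 between different groups within a replicate number and 0.946 between arrays of 1 group. The first 2 principal components, with 30.6% and 23.5% of the variance, separated the replicate numbers.

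The first question was which transcripts each addition line carried at another level than common wheat (CS). Whether these CS plants match the wheat background of the lines is not settled. A difference from CS therefore need not come from the added chromosome. Every line differed from CS, and more probes were higher than lower in each. In limma with Benjamini-Hochberg adjustment, 93 probes were higher and 52 lower in 1HS, 133 and 68 in 2H, and 130 and 80 in 3H. The counts were 97 higher and 48 lower in 4H, 113 and 72 in 5H, 116 and 52 in 6H, and 111 and 45 in 7H. Leaving out 1 of the 3 CS arrays, which leaves fewer arrays in the fit, lowered the number of lower probes to between 25 and 37 in 1HS, 38 and 46 in 2H, 42 and 49 in 3H, 27 and 36 in 4H, 43 and 52 in 5H, 31 and 36 in 6H, and 29 and 38 in 7H. The number of higher probes fell as well in every line, to as few as 87 in 2H, without CS replicate 1. Most of the called differences were large: 138 of the 145 calls in 1HS and 152 of the 156 in 7H were at least 2-fold, and the median higher call ranged from 2.46 on the log2 scale in 2H to 3.21 in 5H. The fit favours large differences, since it recovered 16 of 100 simulated 2-fold changes. With only probes detected on all 6 arrays tested, 58 were called in 1HS and 60 in 7H. The sizes of other calls can rest partly on background values.

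With the replicate number as a block the counts rose in every line. They became 182 higher and 319 lower in 1HS, 1197 and 733 in 2H, 822 and 428 in 3H, 482 and 242 in 4H, 763 and 531 in 5H, 767 and 214 in 6H, and 342 and 163 in 7H. All calls made without the block were made with it, in the same direction. In 1HS, 2H, 3H and 4H the block leaves in any difference between their slides and those of CS. With the slide as a random block instead, 125, 132, 169 and 116 probes were called in those lines, fewer than without a block. In 5H, 6H and 7H it gave 1442, 990 and 571. The rise in 1HS, 2H, 3H and 4H therefore cannot be told apart from differences between slides. The share of higher calls in 1HS was 64.1% without the replicate block and 36.3% with it. It was 55.8% with the block on the 6 arrays of 1HS and CS alone, 29 higher and 23 lower. Array 1HS replicate 2 had 26292 probes well above background, against at least 30720 on the others of that replicate number. With it and 4H replicate 3 left out, the block gave 147 higher and 193 lower in 1HS (43.2%), so the balance of directions in that line is not settled. Under normexp background correction the share of higher calls was 83.1% in 1HS, 71.0% in 2H, 77.8% in 3H, 81.7% in 4H, 78.8% in 5H, 85.9% in 6H and 80.7% in 7H, against 64.1%, 66.2%, 61.9%, 66.9%, 61.1%, 69.0% and 71.2% with the processed signal.

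**Figure D1:**
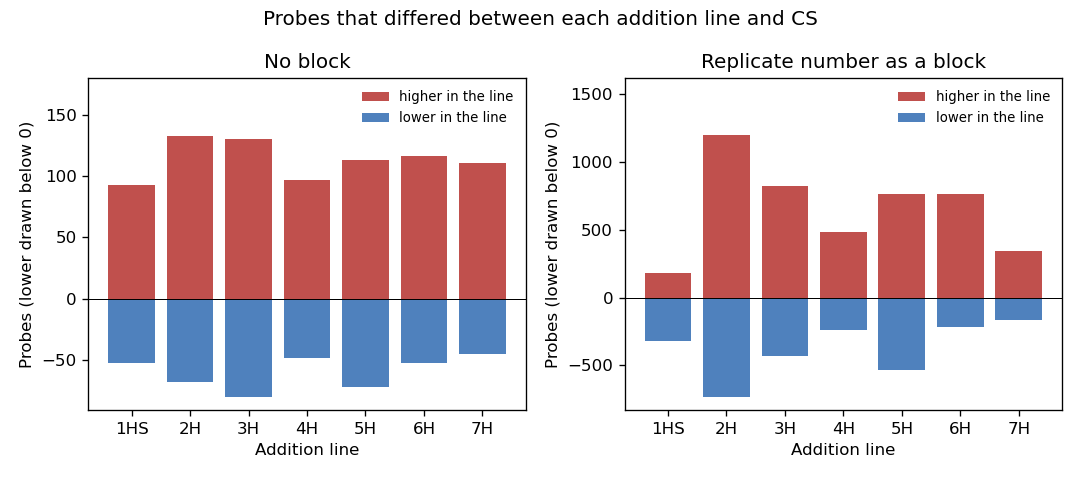
Number of probes higher (above 0) and lower (below 0) than CS in each addition line, in limma at an adjusted p below 0.05, without a block and with the replicate number as a block; the vertical scales differ. Without the block, 2H has 133 higher probes and 3H has 80 lower ones, and with it the counts reach 1197 and 733 in 2H.

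The same probes had the largest fitted differences among higher probes in all 7 lines. Where a group was not well above background on every array, a fitted difference partly rests on background values, so the order of such probes is not established. Probe whsh_allContig1159 (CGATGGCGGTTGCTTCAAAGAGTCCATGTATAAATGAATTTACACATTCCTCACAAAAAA) had a scaled log2 signal of 5.99 ± 0.53 (SD, n = 3) in 1HS against -6.23 ± 2.80 (SD, n = 3) in CS, where 2 of 3 arrays were well above background. Its log2 difference from CS was 12.22 in 1HS, 12.16 in 2H, 12.20 in 3H, 12.47 in 4H, 12.39 in 5H, 12.39 in 6H and 12.48 in 7H, each with an SE of 0.85, and the highest limma adjusted p over the lines was 3.29e-08. Within a scan day the smallest difference of any line was 9.17. Probe wheat0130Contig11843 (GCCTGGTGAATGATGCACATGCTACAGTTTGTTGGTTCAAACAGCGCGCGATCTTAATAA) was higher than CS by 11.37 in 1HS, 11.45 in 2H, 11.35 in 3H, 11.30 in 4H, 11.33 in 5H, 11.19 in 6H and 11.13 in 7H on the log2 scale, with an SE of 0.31 in each. It was well above background on all 21 line arrays and on 1 CS array, and its day-by-day differences were at least 10.43 in each line.

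Among lower probes, MUGEST2003_23lib_Contig8600_p_1414 (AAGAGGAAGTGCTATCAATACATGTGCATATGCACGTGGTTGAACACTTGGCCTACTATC), with the largest fitted fall in 1HS, 2H, 3H, 4H, 6H and 7H, was at 2.87 ± 0.85 (SD, n = 3) in CS. It was not well above background on any array of 1HS, 3H, 4H or 7H, and was lower there by at least 326-fold, 374-fold, 368-fold and 335-fold. In 2H and 6H, 1 of 3 arrays measured it, with log2 differences of -9.94 and -9.86. In 5H all 3 arrays measured it, at -0.14 ± 1.26 (SD, n = 3). That was 8.02-fold below CS, and lower on each of the 3 scan days, with a limma adjusted p of 0.409 and of 0.0388 with the replicate block. Probe wheat0130Contig5372 (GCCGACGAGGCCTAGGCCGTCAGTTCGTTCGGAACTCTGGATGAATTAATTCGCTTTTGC), at 2.00 ± 0.41 (SD, n = 3) in CS, was lower by at least 223-fold in 2H, 187-fold in 5H, 206-fold in 6H and 185-fold in 7H. In 3H and 4H, 1 of 3 arrays measured it, with log2 differences of -8.76 and -8.85. Probe wheat0130Contig12368 (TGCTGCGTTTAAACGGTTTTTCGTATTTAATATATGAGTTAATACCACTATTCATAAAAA), among the named ones in 1HS and 5H, was at 0.39 ± 0.46 (SD, n = 3) in CS and below background in both lines, by at least 58.5-fold and 60.9-fold. Its limma adjusted p in 1HS was 5.20e-04, and it rose to 0.105 under normexp background correction.

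The lines were then compared with each other in which probes had changed. Of the tested probes, 92 were higher and 50 lower than CS in at least 4 lines, and 73 and 21 were so in all 7. Without CS replicate 1, 2 or 3, 76, 78 and 77 were higher and 27, 29 and 30 lower in at least 4 lines. Independent lists of these sizes would share 3.51e-04 higher and 2.62e-05 lower probes in 4 lines. In 100 simulations of 8 unchanged groups with shared CS arrays, no probe was called in 4 lines. At most 2 probes were called higher, and at most 2 lower, in any line. That 0 was therefore nearly fixed in advance and does not measure sharing through CS. Part of the excess can come from the CS arrays, which all comparisons share and which are too few to split. The log2 differences of 2 lines correlated across probes at 0.60 to 0.81, against a mean of 0.50 in the simulations. Their mean covariance was 0.288 against 0.147 simulated, a difference of 0.141. The simulations held no replicate effects, though replicate numbers pair the arrays here, so the simulated correlation and covariance are not a matched baseline. With the replicate number as a block, 450 probes were higher and 160 lower in at least 4 lines.

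**Figure D2:**
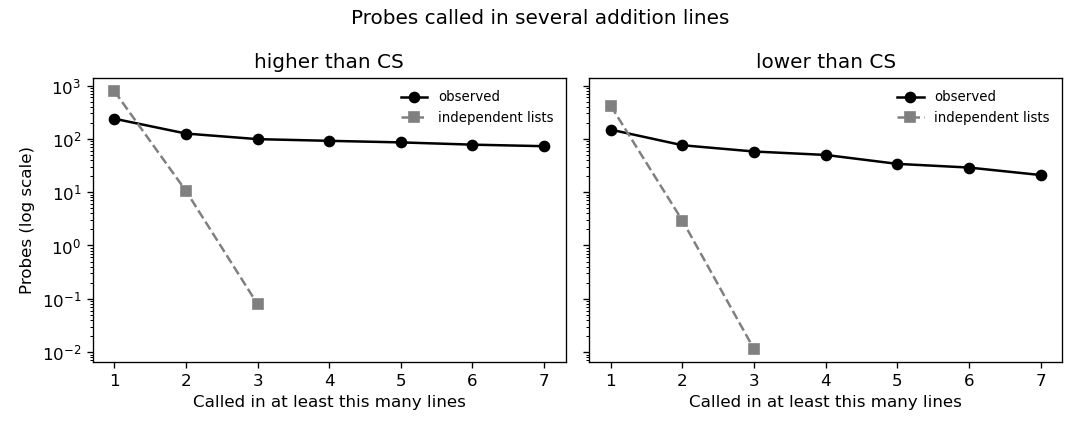
Number of probes called higher (left) or lower (right) than CS in at least the number of lines on the horizontal axis, on a log scale, beside the number expected if the lists were independent, drawn down to 0.01. The observed counts stay at 73 higher and 21 lower probes in all 7 lines.

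The 5 probes called in all lines with the largest mean fitted difference, each with at least 1 CS array not well above background, were higher in the lines. Their order, and which probes are among the 5, depend on those background values. Besides both already given, wheat0130Contig2518 (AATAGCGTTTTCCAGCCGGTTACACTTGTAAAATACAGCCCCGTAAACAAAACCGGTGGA) and wheat0130Contig11195 (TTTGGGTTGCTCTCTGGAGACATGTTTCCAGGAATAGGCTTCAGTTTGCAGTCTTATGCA) were well above background on all 21 line arrays and on no CS array. They were higher in the lines by at least 291-fold and 209-fold. MUGEST2003_23lib_Contig12312_256 (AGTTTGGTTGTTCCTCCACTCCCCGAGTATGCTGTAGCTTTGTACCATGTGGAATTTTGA) had a mean log2 difference of 10.28 and 2 CS arrays above background.

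CS itself stood apart from the 21 line arrays at a set of probes, though not on every measure. On the first 2 principal components, 7H replicate 3, at 50.7 and -56.5, lay near CS replicate 3, at 46.6 and -60.7. The 3 CS arrays lay above all 21 by more than 2-fold at 21 probes, and below all 21 by more than 2-fold at 64. By more than 4-fold the counts were 13 and 42. In 100 draws of 3 arrays from different groups, 1 from each replicate number, the highest number of such probes was 1. Each draw left the other arrays of its groups among the rest, which holds such counts low. In CS, 6 probes were detected on its 3 arrays and nowhere else, among them wheat0130Contig12368 at 0.39 ± 0.46 (SD, n = 3), at least 64.6-fold above the 21 line arrays. At 12 probes no CS array was well above background while all 21 line arrays were, and the same held for 5H against the other arrays at 1 probe and for no other line.

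**Figure D3:**
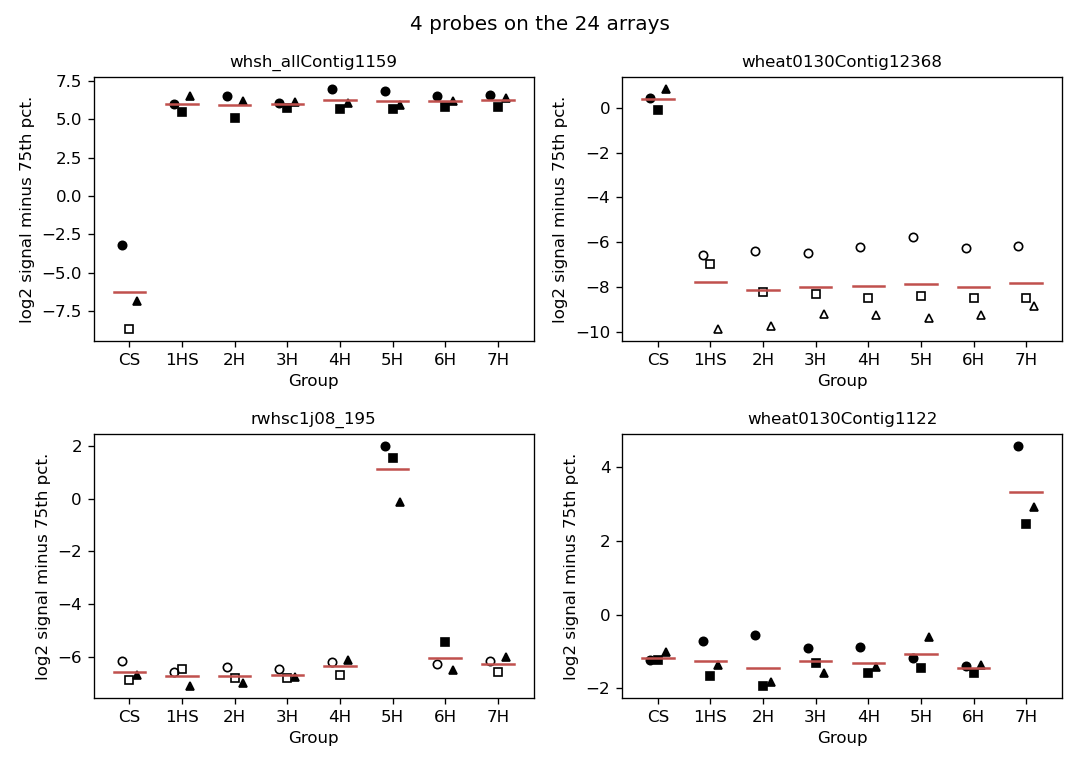
Scaled log2 signal (log2 signal minus the 75th percentile of the array) of 4 probes on the 24 arrays; circles, squares and triangles are replicates 1, 2 and 3, open symbols are not well above background, and bars are group means. The upper probes separate CS from all lines, and the lower ones separate 5H (mean 1.13) and 7H (mean 3.31).

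Transcripts found in the added chromosome alone, if the array has probes for them, would be detected in the line that carries it and in no other. A transcript of that chromosome that binds a probe detected in other groups would not be counted. The probes could not be assigned to chromosomes, so the counts do not measure expression from the added one. One probe met the criterion used here, well above background on all 3 arrays of a line and on none of the other 21. It was wheat0130Contig6535 (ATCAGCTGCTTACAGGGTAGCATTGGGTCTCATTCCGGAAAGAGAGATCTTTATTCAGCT) in 3H, at -3.23 ± 0.08 (SD, n = 3) and at least 5.29-fold above the other arrays, with a limma adjusted p of 0.0283 against CS. Its limma adjusted p was 3.35e-06 with the replicate block, and above 0.05 without any 1 of the 3H arrays. With the significance flag of the files as the criterion, no probe met it in 3H and 1 did in 6H. The count was 0 in 1HS, 2H, 4H, 5H, 6H and 7H, against 6 in CS, and 100 draws of 3 arrays from different groups gave a mean of 0.13 and at most 7. In 100 draws that also took 1 array from each replicate number, as the groups do, the mean was 0.01 and the highest count 1. All these draws left other arrays of the drawn groups among the rest, which holds the counts low. Leaving out the line's own array of replicate 1, the replicate with the fewest probes above background, raised the count. It became 11 in 2H, 4 in 6H, 3 in 1HS and in 5H, 2 in 3H, and 1 in 4H and in 7H. Asking for 2 arrays in place of 3 can only keep or raise the count, and no draws of 2 arrays were made.

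Each line was also compared with the mean of the other 6 lines, which uses no CS array. Lines 1HS, 2H, 3H and 4H never shared a slide with 5H, 6H and 7H. These contrasts therefore carry part of any difference between the slides of a day, which the replicate block leaves in. In limma, 57 probes were higher and 53 lower in 5H, 51 and 30 in 7H, 44 and 34 in 3H, 17 and 3 in 6H, and 16 and 3 in 2H. No probe was called in 1HS or 4H, where 601 and 545 probes had an unadjusted p below 0.05. With the replicate number as a block, 655 were higher and 385 lower in 7H, 362 and 437 in 5H, 291 and 170 in 3H, 187 and 149 in 2H, 154 and 42 in 6H, 2 and 28 in 1HS, and 5 and 5 in 4H. Of the calls against CS, 58 of 210 in 3H, 55 of 185 in 5H, 39 of 201 in 2H, 31 of 156 in 7H and 24 of 168 in 6H were also called in that direction against the other lines with the block. In 1HS it was 2 of 145, and in 4H 1 of 145.

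Line 5H had the most probes that lay apart from all 21 other arrays by more than 2-fold, 12 above and 1 below. Of these, rwhsc1j08_195 (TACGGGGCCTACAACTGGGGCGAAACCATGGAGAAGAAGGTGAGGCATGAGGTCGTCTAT), was at 1.13 ± 1.12 (SD, n = 3) in 5H and -6.47 ± 0.39 (SD, n = 21) elsewhere, where 8 of 21 arrays were well above background. Its limma adjusted p against CS, where 1 of 3 arrays was well above background, was 9.67e-10. MUGEST2003_23lib_Contig20900_455 (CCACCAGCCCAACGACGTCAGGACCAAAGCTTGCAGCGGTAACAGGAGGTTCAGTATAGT) was at 2.72 ± 0.15 (SD, n = 3) against -4.20 ± 1.15 (SD, n = 21). The probe below all others, MUGEST2003_23lib_Contig4242_1348 (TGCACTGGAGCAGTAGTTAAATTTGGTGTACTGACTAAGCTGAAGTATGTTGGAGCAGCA), was at -3.72 ± 0.56 (SD, n = 3), with 2 of 3 arrays well above background, against -0.82 ± 0.56 (SD, n = 21).

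Line 3H had 7 such probes, all above. Probe rwhr16c10 (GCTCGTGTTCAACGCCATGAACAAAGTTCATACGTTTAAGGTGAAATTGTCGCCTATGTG) was at -1.97 ± 0.36 (SD, n = 3) in 3H and -7.24 ± 1.04 (SD, n = 21) elsewhere, with 3 of the 21 arrays well above background. Probe wheat0130Contig4063 (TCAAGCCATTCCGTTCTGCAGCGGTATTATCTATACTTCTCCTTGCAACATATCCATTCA) was at -0.54 ± 0.34 (SD, n = 3) against -5.85 ± 1.18 (SD, n = 21). Line 7H had 4, all above. Its wheat0130Contig1122 (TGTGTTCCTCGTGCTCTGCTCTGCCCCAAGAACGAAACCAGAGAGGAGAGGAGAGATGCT), measured on all 24 arrays, was at 3.31 ± 1.11 (SD, n = 3) against -1.28 ± 0.38 (SD, n = 21). It differed from CS by 4.47 on the log2 scale, with an SE of 0.44 and a limma adjusted p of 4.27e-06.

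Line 6H had 1 probe above and 2 below. Probe MUGEST2003_23lib_Contig5356_332 (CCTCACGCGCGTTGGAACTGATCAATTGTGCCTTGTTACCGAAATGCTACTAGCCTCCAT) was at -0.62 ± 0.05 (SD, n = 3) in 6H against -4.31 ± 1.01 (SD, n = 21). Probe wheat0130Contig1488 (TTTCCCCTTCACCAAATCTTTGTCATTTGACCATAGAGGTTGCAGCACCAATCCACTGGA) was at -3.71 ± 0.48 (SD, n = 3) against -1.59 ± 0.28 (SD, n = 21), and whrd18d07_341 (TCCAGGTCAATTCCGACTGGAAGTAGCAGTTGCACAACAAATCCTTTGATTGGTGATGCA) at -5.68 ± 0.48 (SD, n = 3) against -3.62 ± 0.31 (SD, n = 21). Each was well above background on 2 of the 3 6H arrays. Under normexp background correction, whrd18d07_341 turned to 0.58 above CS on the log2 scale, and the limma adjusted p against CS was 0.111 for MUGEST2003_23lib_Contig5356_332 and 0.489 for wheat0130Contig1488. Line 2H had 1 probe above, rwhyd18h04 (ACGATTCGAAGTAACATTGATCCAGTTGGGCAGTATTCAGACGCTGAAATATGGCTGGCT), at -1.06 ± 0.29 (SD, n = 3) against -3.48 ± 0.36 (SD, n = 21). Under normexp, rwhyd18h04 in 2H, rwhr16c10, wheat0130Contig4063 and wheat0130Contig6535 in 3H, and MUGEST2003_23lib_Contig4242_1348 in 5H also lost their calls against CS. Lines 1HS and 4H had 0. In the draws of 3 arrays from different groups, at most 1 probe was separated by more than 2-fold, as many as in 2H. Each draw left the other arrays of its groups among the rest, which holds such counts low, so the draws are a weak chance level.

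Of the 6 probes the files name after cold- and drought-response genes, RD29A, cor47 and DREB2B were well above background on no array, DREB2A on 5 of 24 and Wcor15 on 15. Whether these probes match wheat transcripts was not checked, so a lack of signal does not show that such genes were silent. RD29B was the 1 of them tested. It was well above background on 23 arrays, at -4.39 ± 0.95 (SD, n = 3) in CS, and was called in 0 of the 7 lines in limma and in 3 with the replicate number as a block.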

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

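Fits with 2 choices changed together, those without the arrays 1HS replicate 2 and 4H replicate 3, normexp for the shared count, and CS arrays left out of it were chosen after seeing the data. Counts here are of changed probes in the order 1HS, 2H, 3H, 4H, 5H, 6H and 7H, where they were 145, 201, 210, 145, 185, 168 and 156. Quantile normalization, scaling by the median of probes detected on all arrays, the series matrix, no filter on dim probes and a 2-fold minimum kept every count within 1.5 times. With the replicate block the counts were 501, 1930, 1250, 724, 1294, 981 and 505, and with a 2-fold minimum as well 379, 1218, 775, 551, 723, 693 and 329. The block removes the spread between scan days, and not that between the slides of a day. Normexp gave 83, 93, 108, 82, 85, 92 and 88, probes detected on all 6 arrays 58, 95, 108, 62, 74, 78 and 60, and the 6 arrays alone 59, 80, 90, 68, 102, 83 and 78. The stricter filter tests fewer probes and the last fit has fewer arrays; the cause under normexp was not tested. The 6 arrays with the replicate block gave 52 in 1HS, 63 in 4H and 256 in 6H. Against the other 6 lines the counts were 0, 19, 78, 0, 110, 20 and 81, and with the replicate block 30 in 1HS, 336 in 2H, 461 in 3H, 10 in 4H, 799 in 5H and 1040 in 7H. Slide as a random block gave 125, 132, 169, 116, 1442, 990 and 571. These counts were lower than without a block in 1HS, 2H, 3H and 4H, which share no slide with CS. Slide as a fixed block gave 1702, 1206 and 544 in 5H, 6H and 7H, the lines that share slides with CS. Without the arrays 1HS replicate 2 and 4H replicate 3 no count moved by over 1.5 times, and with the replicate block as well the counts were 340, 2306, 1367, 433, 1451, 1185 and 487, with 147 higher and 193 lower in 1HS. Leaving out each array in turn gave 125 to 187 in 2H, the lowest without CS replicate 1, and no other total moved by over 1.5 times. The lower probes alone did without a CS array, as given in the report, and so did the higher probes in 2H, from 133 to 87. Without a line array the lower probes also moved that far in some lines, as from 80 to 43 in 3H without 3H replicate 1. Probes detected in a single line numbered 0 to 3 in 1HS, 0 to 11 in 2H, 1 to 2 in 3H, 0 to 1 in 4H, 0 to 3 in 5H, 1 to 4 in 6H and 0 to 1 in 7H when 1 replicate of the line was left out. With the significance flag as the criterion the count was 0 in 3H and 1 in 6H. Probes changed in at least 4 lines, 142 in all, were 94 in all 7 lines, 610 with the replicate block and 83 under normexp. Against the other 6 lines they were 0, and 2 with the replicate block. A change that the lines share cancels in those contrasts, so these counts cannot show whether the sharing comes from CS. The probes named for a difference from CS or for setting a line apart were refitted against CS, in the lines they were named for, under 10 other settings each; those the files name after genes and those given for 4H replicate 3 were not. Of these 610 values, 15 lost their call, 2 gained one and 1 changed direction, whrd18d07_341 in 6H, at 0.577 under normexp. Of the lost calls 8 were under normexp, wheat0130Contig12368 in 1HS among them, and wheat0130Contig6535 in 3H lost its call under 6 settings. Both gains were of MUGEST2003_23lib_Contig8600_p_1414 in 5H. Replicate 1 had the fewest probes well above background, which limits what can be detected on all 3 arrays of a line. Gene lists, markers of other tissues and chromosome groups were not run, because the probes could not be assigned to genes.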

Other observations

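All tests reported here were chosen after the results they bear on had been seen.

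Probes chosen on 2 replicates told CS, 3H, 5H and 6H, and mostly 7H, from the rest of the remaining replicate, and were too few in 1HS and 4H to show whether they did. Probes that separated a group by more than 2-fold on 2 replicates were looked up in the one left out, where 1 array in 8, or 12.5%, would be the most extreme by chance. For CS, 96 of 96, 94 of 94 and 93 of 94 probes were most extreme in the CS array. For 5H it was 21 of 23, 15 of 16 and 18 of 18, for 3H 16 of 19, 10 of 11 and 9 of 9, and for 7H 6 of 10, 7 of 7 and 6 of 6. For 6H it was 4 of 5, 4 of 5 and 5 of 5, and for 2H 3 of 4, 2 of 2 and 3 of 6. These sets are small in 2H and 6H. For 1HS it was 1 of 1 and 1 of 4 with replicates 1 and 3 left out, and for 4H 1 of 4 with replicate 3 left out. The other rounds of 1HS and 4H found 0 probes.

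CS stood apart from the lines at 85 probes, 21 higher and 64 lower than on all 21 line arrays by more than 2-fold. At the 85 probes that separated CS from the 18 arrays of the other lines, 4H, which lay at the same slide position as CS on each scan day, showed a median share of 0.0135 of the CS shift (quartiles -0.0114 and 0.0525), which argues against the position as the cause. At the 93 probes chosen on 1HS, 2H, 3H and 4H alone, the 3 lines on the CS slides showed 0.00995, with 1 probe over 0.5, which argues against the slides. The probes were also not gathered in 1 region of the array: the median distance to the nearest other was 12.2 spots, against 11.4 in random sets of as many probes. Of 100 triples of arrays, the real one gave 85 separated probes and the highest of the others 1. Each of the others took its arrays from 3 different groups, so most CS arrays stayed among the rest. The draws argue against a chance triple of arrays but do not exclude it. A difference in seed stock or genotype between the CS plants and the wheat background shared by the lines may be the cause, a hypothesis that no test here addressed because CS was sampled as 1 group; contamination or mislabelling shared by the 3 CS arrays also stays open.

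Probes that set a line apart from all 21 other arrays, by any margin, were more often higher than lower in it, 372 against 154 over the 7 lines (70.7% higher), although 2H had 28 higher and 30 lower. Dim probes, which can rise but not fall, do not account for all of this: among the 19751 probes well above background on all 24 arrays, 279 were higher and 109 lower, or 71.9% higher, with 13 and 28 in 2H. Lines 1HS and 4H add only 3 and 5 probes. Calls against the other 6 lines with the replicate number as a block did not keep this direction in every line, with 362 higher and 437 lower in 5H and 2 and 28 in 1HS, and with a 2-fold minimum 63 and 79 in 3H and 96 and 104 in 5H. The 21 line arrays were also put into 7 groups of 3 different lines, 1 array from each replicate number. Of 100 groupings including the real one, 7 gave as high a share of higher probes, up to 81.8%, so chance is not excluded for the share. The mixed groupings separated few probes, at most 54 against 526, so their shares rest on small sets. Their median share was 42.3%. The excess of higher over lower probes was 218 in the real grouping and at most 14 in the mixed ones. That excess also grows with the number of probes separated. No biological explanation was tested. Probes are not independent of each other, so the shares carry no error.

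The array labelled 4H replicate 3 differed from the other 4H arrays at 4 probes, 3 higher and 1 lower in those arrays, that set them apart from the 14 others of replicates 1 and 2 by more than 2-fold. It lay nearer to the other groups at all 4, though at wheat0130Contig1625 its -4.98 was above every other replicate 3 array, the highest of which was at -5.48. At one of the 4, whh6m24, the scaled log2 signal was 1.84 and 3.80 in replicates 1 and 2 and -1.52 in replicate 3. Such a set is not beyond chance, since 3 of 42 pairs of arrays from different lines gave as many probes, up to 8. A swap with another replicate 3 array therefore cannot be told apart from it, with at most 1 of the 4 probes on the 4H side in any of them. A CS plant under that label is argued against by the 85 probes that separated CS from the other 20 line arrays, chosen without this one, where it showed a median share of -0.0302 of the CS shift and no probe was over 0.5.

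The 6 arrays of each comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. In each of the 7 comparisons 1 of the 10 splits, the real one, gave as many probes as the labels did. The real counts were 145 in 1HS, 201 in 2H, 210 in 3H, 145 in 4H, 185 in 5H, 168 in 6H and 156 in 7H, and the highest of the other splits was 1 in 2H and 0 in the other 6. Among the 4 splits that part all replicate pairs, the 3 other than the real one gave 0 in every line. With the replicate number as a block, a split in 1HS that put 1HS replicate 1 with CS replicates 1 and 2 called 230 probes, against 501 for the real one. That split does not part all replicate pairs. It also leaves 1HS replicate 2, an array with few probes well above background, in the other group. Why it called that many was not tested.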
